A study of Homo sapiens with 3 samples.

How the data were processed

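RNA (total RNA per the sample labels, mRNA per the series design, so the selection is unknown) of the WT line and the 2 Ara-C resistant lines 3R and 50R was sequenced, with 1 library per line, on libraries made with a standard Illumina protocol, per the labels' protocols. The authors quantified each library with Salmon, per the file headers and the submitters' processing notes, and deposited 1 value per Ensembl gene ID. The deposited values were taken as TPM because they are not whole numbers and sum to the same total in each library, 999999.9 in WT; the headers name the tool but not the unit. The Salmon version, its index, the genome build, the annotation release and how transcripts were joined to genes are not given in the sources used here. TPM corrects for transcript length and divides by the library total, so abundant small RNAs lower every other value, and it does not keep read counts. Depth is therefore unknown, and no counting intervals or detection floors are given. A gene at exactly 0 is described as listed at 0.

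The files hold 63677 gene IDs with symbols. TPM was summed over IDs that share a symbol, which gave 56636 symbols, 3077 of them with several IDs. Gene IDs were matched to GENCODE release 29 (52526 IDs) and to a table of current symbols (52181 IDs), which were used only for gene type, chromosome, gene order, transcript length and GC content. No coordinates are printed, since the authors' build is not given. Symbols are printed as in the files. Libraries were scaled by a trimmed mean of log ratios (30% of log ratios and 5% of mean levels trimmed at each end, unweighted), with factors of 1.00 for WT, 1.08 for 3R and 1.15 for 50R. Genes with a mean scaled TPM of at least 1 over the 3 libraries were compared (15756), on the scale log2(scaled TPM + 1).

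Pairs of libraries were described by folds, with a size rule of 2-fold and no test. The planned design assumed estimated counts and a count model for the comparison of both resistant lines with WT; as the files hold TPM, limma was used in its place on log2(scaled TPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05, as the plan allowed for that case. edgeR and DESeq2 were not used. Of 33 gene lists fixed before the data were examined, 28 had at least 5 measured members. Each list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 10 groups, and a list was said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. Genes named in the text followed a rule set at the same time: 9 genes of CD123 and Ara-C metabolism in every comparison; the 10 highest and 10 lowest folds per pair of libraries among genes with a symbol and at least 20 TPM in 1 of the 2 libraries; up to 4 members of each list with the largest fold; up to 10 genes per direction in limma's test; and up to 3 genes per direction at least 4-fold from WT in each line in opposite directions, of which there were 0. Y-linked genes and XIST were left out. The text names fewer list members than the rule allows, and any gene outside the rule is said to be so or is a member counted in a list. Some genes that the rule names are not reported here.

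The overlap of the 2 lines was set beside 100 simulations of 3 libraries with no effect, with the spread taken from 3R against 50R. On simulated data with 200 changed genes among 15756, over 20 simulations, limma recovered 39.1% of log2 changes of 1, 99.3% of changes of 2 and 100% of changes of 3. On average 12.6% of its calls were false there, between 0.7% and 21.6%, above the nominal share. In 100 random lists of 25 genes from 3R against WT, 4% passed the percentile limits with no shift and 95% with a shift of 0.3 log2. The share with no shift follows from the limits themselves, since genes were drawn at random. It does not show how often lists of genes that vary together would pass with no effect. Alternatives covered the scaling (median of ratios, or none), the filter (none, or at least 10 TPM), pseudocounts of 2, 0.5 and 0.1, limma with a mean trend and another library as the lone sample. Alternatives added after seeing the data were each gene ID on its own, protein-coding genes only, and folds corrected for GC content, where the median difference from WT in each of 50 bins of transcript GC content was taken out of 3R and 50R. For limma, the folds with and without the GC correction were also tested with the prior of the other fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, were used.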

Results

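Gene expression was measured by RNA sequencing in OCI-AML2, an established human acute myeloid leukaemia cell line, and in 2 derivatives that resist cytarabine (Ara-C), the nucleoside analogue at the centre of leukaemia chemotherapy. The parental line is called WT here and the derivatives carry the submitters' names 3R and 50R. What the numbers 3 and 50 stand for is not given in the labels. Each line had 1 library, so there were no replicates, a difference between 2 libraries has no replicate check, and folds are given without p-values. The deposited values, for 63677 gene IDs, were taken as TPM, abundances corrected for transcript length, since their unit is not named. They sum to the same total in every library and keep no record of depth, so the depth is unknown. Values above 0 were listed for 38760 IDs in WT, 38815 in 3R and 38642 in 50R. The labels give total RNA as the molecule while the series design speaks of mRNA, so which RNA was selected is not known. Small RNAs took 42.1% of the WT total, 41.4% of the 3R total and 42.6% of the 50R total. RN7SL1, RN7SL2 and RN7SK alone, the RNAs of the signal recognition particle and of a transcription elongation regulator, made up 28.3%, 28.2% and 30.3%. Across genes, Pearson's r of log2 values was 0.976 between 3R and WT, 0.974 between 50R and WT and 0.978 between 50R and 3R. Levels below are scaled TPM, and folds are differences of log2(scaled TPM + 1) over the 15756 genes with a mean of at least 1, a scale that understates the change of low genes.

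The series title concerns leukaemia cells that carry CD123 and resist chemotherapy. IL3RA (ENSG00000185291), which encodes CD123, the alpha chain of the interleukin-3 receptor, stood at 6.44 TPM in WT, 5.62 in 3R and 2.73 in 50R, a log2 fold of -0.17 in 3R and -1.0 in 50R. In limma's test of both resistant lines against WT its adjusted p was 0.86, and the 50R level had no replicate check. Of the 24 leukaemia stem cell surface antigens listed beforehand, 14 were measured, and 12 of these were below WT in 50R. Their median log2 fold was -0.42 in 50R, at percentile 0.03 of random lists matched on expression, and -0.15 in 3R, at percentile 6.43. CD70, a tumour necrosis factor family ligand, fell from 70.5 TPM in WT to 12.2 in 3R and 9.72 in 50R (limma, adjusted p = 4.44e-05), the 1 member called over all genes, and 2 members fell with p adjusted over the list alone. CD44, a hyaluronan receptor, went from 213 TPM in WT to 129 in 3R and 91.9 in 50R, with log2 folds of -0.73 and -1.21. ITGA6, an integrin chain, was at 2.77, 2.62 and 1.33 TPM. CD34, a stem cell marker named after its values were seen, was listed at 0 in all 3 libraries. For 3R the GC correction described with the comparison of 3R and WT moved the list's median to -0.23, at percentile 0.16.

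Genes that carry Ara-C into cells, activate it or inactivate it differed by less than 2-fold from WT in both lines, apart from SLC28A3 in 3R. DCK (ENSG00000156136), deoxycytidine kinase, which makes the first phosphorylation of Ara-C, was at 14.2 TPM in WT, 8.85 in 3R and 7.85 in 50R, log2 folds of -0.63 and -0.78 (limma, adjusted p = 0.544). SLC29A1, the equilibrative nucleoside transporter ENT1, was at 22.5, 19.5 and 28.1 TPM. SLC28A3, a concentrative nucleoside transporter, was at 11.3, 26.8 and 17.8 TPM, a log2 fold of 1.17 in 3R. CDA, cytidine deaminase, which inactivates the drug, was at 7.52, 7.14 and 10.9 TPM. SAMHD1, which hydrolyses its triphosphate, was at 24.0, 32.2 and 32.9 TPM, and the nucleotidase NT5C2 at 50.0, 66.7 and 55.2. DCTD was at 28.7, 23.6 and 27.9 TPM. The ribonucleotide reductase subunits were at 66.3, 79.0 and 102 TPM for RRM1 and at 62.0, 57.5 and 74.2 for RRM2. NME1, a nucleoside diphosphate kinase, was at 46.9, 41.5 and 80.0 TPM, and TK1, thymidine kinase, at 12.4, 10.7 and 20.4. Of the 20 measured members of the list, limma called 0, over all genes and adjusted over the list alone, and 2 had p below 0.05 before adjustment, DCK (0.0227) and SLC28A3 (0.00861). Their median log2 fold was -0.09 in 3R (percentile 12.48) and 0.24 in 50R (percentile 99.05, and 95.24 after the GC correction). In 50R 12 members were above WT and 8 below, with NME1, TK1 and RRM1 highest (0.76, 0.67 and 0.62) and DCK lowest (-0.78). The 3R sign turned with TPM as deposited (0.01), where the median of all genes moved up by 0.09 log2 in 3R and 0.16 in 50R. It also turned after the GC correction (0.00), and the 3R median stayed within the percentile limits in all 11 settings. Among 9 measured drug efflux pumps the medians were -0.05 in 3R and -0.03 in 50R, at percentiles 35.49 and 39.33. Both signs turned with the same shift of all genes under TPM as deposited (0.06 and 0.16), the 50R sign also after the GC correction (0.00). The efflux list stayed within the percentile limits in the 10 settings where it had a percentile. ABCC1, the multidrug resistance protein, was at 8.22, 7.46 and 5.93 TPM.

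The comparison of 3R with WT asks how a resistant line differs from its parent. MPO, PRTN3, ELANE and CTSG, which encode proteins of the neutrophil primary granule, were far above WT in 3R, but AZU1 of the same granule, named after its values were seen, was not, at 280 TPM against 273. MPO (ENSG00000005381), the peroxidase of that granule, stood at 368 TPM against 29.9 in WT, a log2 fold of 3.58. The granule proteases PRTN3, ELANE and CTSG were at 159, 95.7 and 831 TPM against 27.1, 24.4 and 222. S100A8, a calcium-binding protein of myeloid cells, was at 56.6 TPM against 16.0, and DEFB1, a defensin of epithelia, at 180 against 15.8. SPARC, a matricellular protein, was at 76.6 TPM against 27.5, and CHI3L1, a chitinase-like glycoprotein, at 20.9 against 6.21. MT2A, a metal-binding metallothionein with close paralogs and so uncertain, was at 46.9 TPM against 11.9. On the low side, CD70 was at 12.2 TPM against 70.5, BAX, a pore-forming executor of apoptosis, at 26.7 against 89.2, NT5DC2 at 5.72 against 24.1 and C12orf75 at 16.6 against 49.3. The calcium channel subunit CACNA2D4 was at 63.0 TPM against 157, the membrane metalloprotease MMP14 at 15.9 against 40.6, and ALOX5AP, which serves leukotriene synthesis, at 13.0 against 31.6. HIST1H3F, at 1.05 TPM against 45, and the small RNAs SNORD3C, SNORD3D and MIR3687 (9.97, 28.9 and 19.0 TPM in 3R against 32.7, 3.01 and 62.7) belong to families of near-identical copies, and their values are uncertain. The 7 histone H3 genes together gave 853 TPM in WT and 545 in 3R.

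Of the fixed lists, 5 had medians below the lower percentile limit in 3R and 2 above the upper, out of 28 with at least 5 measured members. p53 target genes, which are transcribed when p53 is active, had a median log2 fold of -0.73 (percentile 0), with all 26 measured members below WT. Cholesterol and fatty acid synthesis genes had a median of -0.36 (percentile 0), with FASN, fatty acid synthase, at 55.5 TPM against 105. NF-kB and inflammatory cytokine genes had a median of -0.38 (percentile 0.01), adhesion and migration genes of -0.31 (percentile 0.12) and glycolysis and hypoxia genes of -0.31 (percentile 0). The NF-kB median was -0.05, at percentile 27.8, with genes of at least 10 TPM. DNA repair and replication stress genes had a median of 0.25 (percentile 100), with 41 of 45 members above WT. Transcripts of the mitochondrial genome, a list fixed as a sign of RNA quality, had a median of 0.31 (percentile 99.95). They can share reads with nuclear copies and are uncertain.

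By the size rule 145 genes were at least 2-fold higher and 174 at least 2-fold lower in 3R than in WT, and 12 and 6 of these were listed at 0 in the lower library. With TPM as deposited the counts were 194 and 141, because scaling moved the median of all genes by 0.09 log2 in 3R and by 0.16 in 50R. Folds in 3R also followed GC content across 14773 genes (Spearman's rho -0.532; genes are not independent replicates). The median log2 fold was 0.21 in the fifth of genes with the lowest GC content, with a median of 39.8% GC, and -0.29 in the fifth with the highest, with 60.9%. For 50R against WT rho was -0.144 and for 50R against 3R it was 0.351. After the median of each GC bin was taken out, a correction chosen after seeing the data, 141 genes were at least 2-fold higher and 142 lower in 3R, and each of the 7 lists above stayed outside the same percentile limit. Their medians then were -0.70 for p53 targets, -0.26 for cholesterol, -0.40 for NF-kB, -0.27 for adhesion, -0.18 for glycolysis, 0.15 for DNA repair and 0.18 for mitochondrial transcripts. 3 further lists then passed a percentile limit in 3R, namely MHC class II presentation (median -0.26), cell cycle and DNA replication (0.08) and the stem cell surface antigens.

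**Figure D1:**
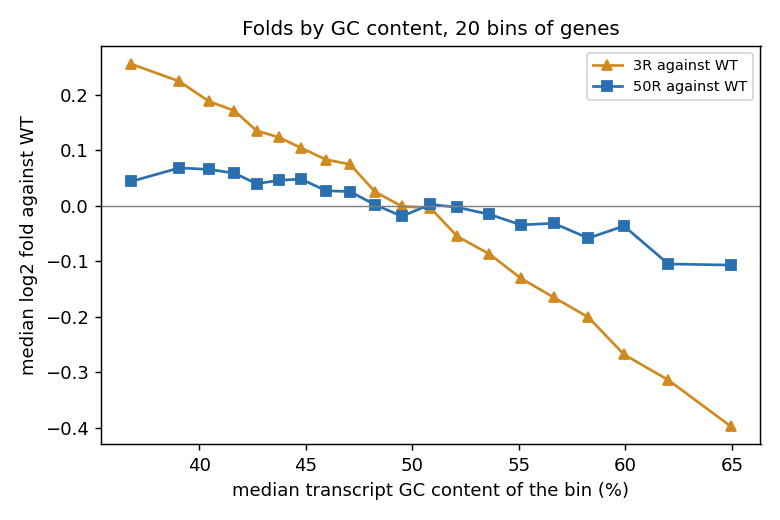
Median log2 fold against WT (vertical axis) of genes grouped into 20 bins by transcript GC content (horizontal axis, percent), with triangles for 3R and squares for 50R. In 3R the bin medians run from 0.26 at 36.8% GC to -0.40 at 64.9%, and in 50R from 0.04 to -0.11.

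In 50R the same 4 genes were far above WT. MPO was at 307 TPM against 29.9 in WT, PRTN3 at 227 against 27.1, ELANE at 130 against 24.4 and CTSG at 732 against 222. AZU1, a neighbour and paralog of PRTN3 and ELANE, was at 322 against 273. DEFB1 was at 196 TPM against 15.8, SPARC at 135 against 27.5, S100A8 at 66.9 against 16.0 and S100A9, its dimer partner, at 254 against 63.5. HSD11B1, which regenerates cortisol, was at 28.2 TPM against 6.30, and RHOXF2, a germ-line homeobox gene with a close paralog, at 26.6 against 7.99. On the low side, CD68, a lysosomal glycoprotein, was at 12 TPM against 48.4, CAPG, an actin-capping protein, at 62.1 against 267, CD300A, an inhibitory receptor, at 6.62 against 24.4, and EVI2A at 22.2 against 111. LYZ, lysozyme, named after its values were seen, was at 2140 TPM against 1080. CIDEB was at 5.31 TPM against 28.2. FTH1, the ferritin heavy chain, was at 39.9 TPM against 145, and GOLGA8A at 6.12 against 24.6; both have near-identical copies and are uncertain. DDIT3 (CHOP), a transcription factor of the stress response, was at 8.59 TPM against 30.2.

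More lists stood apart in 50R than in 3R, 11 below and 6 above the limits, and the difference between these numbers was not tested. Unfolded protein and integrated stress response genes had a median log2 fold of -0.55 (percentile 0), with 29 of 31 below WT, among them ATF5 at 18.6 TPM against 50.9, ATF3 at 1.28 against 4.68 and PPP1R15A at 7.11 against 17.1. p53 target genes had a median of -0.84 (percentile 0), with 23 of 26 members below WT and 3 above. Adhesion and migration genes had a median of -0.64 (percentile 0) and NF-kB and inflammatory cytokine genes of -0.56 (percentile 0). Cholesterol and fatty acid synthesis genes had a median of -0.46 (percentile 0), with CYP51A1 and HMGCS1 at 61.4 and 29.7 TPM against 109 and 52.8. Glycolysis and hypoxia genes had a median of -0.26 (percentile 0.05), with VEGFA, ALDOC and SLC2A3 at 23.9, 24.6 and 14.7 TPM against 67.3, 64.6 and 34.4. MHC class II genes had a median of -0.31 (percentile 1.44), and HLA-DRA, whose reads can be shared with other HLA genes, was at 16.7 TPM against 34.4. The stem cell surface antigens stood apart as given above.

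Above WT in 50R were cell cycle and DNA replication genes, with a median log2 fold of 0.55 (percentile 100) and 42 of 44 members above WT, such as MCM10, CDC20 and CCNB1 at 23.7, 42.8 and 82.3 TPM against 11.3, 23 and 45. CDT1, which licenses replication origins, went the other way, at 33.0 against 60.5. Nuclear genes of oxidative phosphorylation had a median of 0.41 (percentile 100), with 36 of 37 above WT and NDUFA9, NDUFB3 and NDUFB8 of complex I at 82.9, 46.1 and 113 TPM against 47.4, 26.5 and 66.2. The 15 mitochondrial transcripts had a median of 0.76 (percentile 100), with 12 above WT, such as MT-ND5 at 41.9 TPM against 20.6, and 3 below. They can share reads with nuclear copies and are uncertain. RP11-380M21.2 (MTCO2P2), such a copy, was at 0, 5.15 and 8.51 TPM in WT, 3R and 50R. DNA repair genes had a median of 0.37 (percentile 100), with EXO1 and UNG at 46.5 and 21.7 TPM against 23.9 and 12.4. MYC-linked ribosome biogenesis genes had a median of 0.23 (percentile 99.36), with ODC1 at 38.1 TPM against 26.7. Some of the lists past a limit in 50R lay within the limits in 3R, and the difference between the lines was not tested. Their medians in 3R were -0.01 for the stress response (0.09 with TPM as deposited and 0.04 after the GC correction), 0.08 for cell cycle, 0.08 for oxidative phosphorylation and -0.09 for MYC-linked ribosome biogenesis (0.01 with TPM as deposited). They were 0.03 for granulocyte and monocyte maturation, -0.16 for haematopoietic transcription factors, -0.12 for cytokine receptors and JAK-STAT and -0.26 for MHC class II, at percentile 2.52.

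The size rule gave 128 genes at least 2-fold higher and 263 lower in 50R than in WT, and 264 and 188 with TPM as deposited. Several list medians moved with these choices. With TPM as deposited, haematopoietic transcription factors (median -0.18, percentile 1.6) and cytokine receptor and JAK-STAT genes (-0.17, percentile 1.02) were at 0.01 each. Leaving out the scaling moved the median of all genes in 50R up by 0.16 log2, and both lists stayed below the lower percentile limit. Granulocyte and monocyte maturation genes (-0.25, percentile 0.03) turned to 0.10 with genes of at least 10 TPM. The mean of that last list was 0.18, above WT. Means also differed in sign from medians for HOX factors (-0.01) and the stress response (0.02) in 3R, and for MHC class I (0.00) and reference genes (-0.08) in 50R. NF-kB genes were at -0.17 and percentile 3.53 with genes of at least 10 TPM. The haematopoietic factors were at percentile 4.03 after the GC correction, and Ara-C metabolism lost its limit there as given above; the correction left 121 genes higher and 251 lower.

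**Figure D2:**
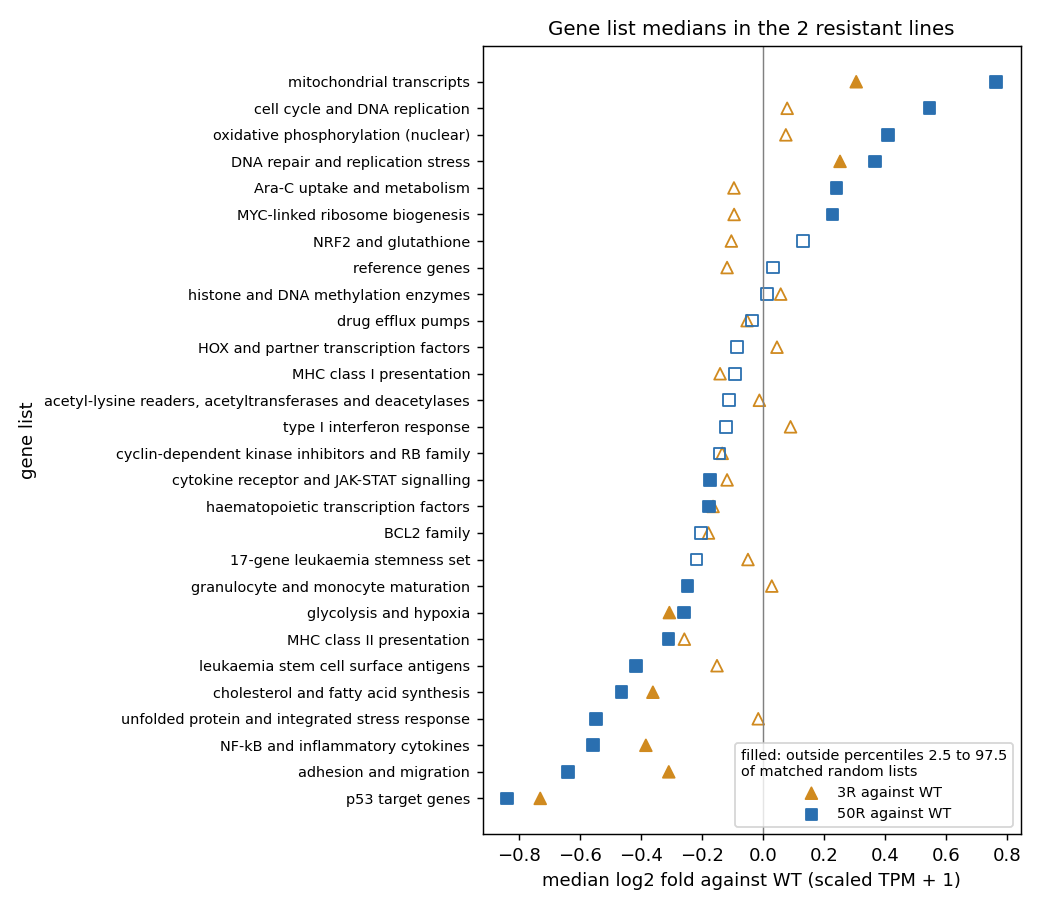
Median log2 fold against WT (horizontal axis, log2 of scaled TPM + 1) of the 28 lists with at least 5 measured genes (vertical axis), with triangles for 3R and squares for 50R, filled where the median lies outside the percentile limits of matched random lists. p53 target genes lie lowest in both lines, at -0.73 and -0.84, and mitochondrial transcripts highest, at 0.31 and 0.76.

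The remaining lists stayed within the percentile limits in both lines. Their medians in 3R and 50R were -0.05 and -0.22 for the 17-gene stemness set, 0.05 and -0.08 for HOX and partner factors, -0.01 and -0.11 for acetyl-lysine readers, acetyltransferases and deacetylases, and 0.06 and 0.01 for histone and DNA methylation enzymes. They were -0.18 and -0.20 for the BCL2 family, -0.13 and -0.14 for cyclin-dependent kinase inhibitors and the RB family, -0.14 and -0.09 for MHC class I presentation, and -0.12 and 0.03 for reference genes. For type I interferon response genes they were 0.09 and -0.12, and for NRF2 and glutathione genes -0.10 and 0.13. With TPM as deposited the sign turned in 3R for the stemness set (0.04) and NRF2 genes (0.00). In 50R it turned for HOX factors (0.08), kinase inhibitors (0.01), MHC class I (0.16) and interferon genes (0.01), and in both lines for the acetylation list (0.09 and 0.08). Leaving out the scaling moved the median of all genes up by 0.09 log2 in 3R and 0.16 in 50R, so these turns follow a shift common to all genes. Among these lists only the interferon genes in 50R then passed a percentile limit, the lower one. The GC correction turned the sign for the stemness set (0.00), the acetylation list (0.00), kinase inhibitors (0.01) and MHC class I (0.03) in 3R. HDAC9, a deacetylase, was at 22.1 TPM in WT, 16.0 in 3R and 12 in 50R. EZH1, a histone methyltransferase, was at 15.6, 14.8 and 8.74, and PBX3, a HOX partner, at 50.9, 61.8 and 51.9. The stemness gene CPXM1 was at 2.56, 0.715 and 0.354 TPM. Few genes of the other lineages reached a mean of 1 TPM, with 2 of 16 erythroid, 4 of 12 megakaryocyte, 3 of 16 T and NK, 2 of 11 B lymphocyte and 4 of 16 fibroblast and epithelial markers measured. The highest in each group were TFRC, also used by any dividing cell (251 TPM in 50R), NFE2 (6.88 in 3R), NKG7 (43.4 in 3R), CD79B (2.37 in 50R) and ACTA2 (4.38 in WT).

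The comparison of 50R with 3R sets the resistant lines against each other. Metallothionein and stress genes were lower in 50R: MT2A was at 4.15 TPM against 46.9 in 3R, MT1X at 7.36 against 38.4 and MT1E at 22.0 against 63.3, all members of a family with near-identical copies and so uncertain. DDIT3 was at 8.59 TPM against 32.6, EVI2A at 22.2 against 77.4, CHI3L1 at 6.75 against 20.9 and SLC6A8, the creatine transporter, which also has copies, at 11.6 against 29.5. Higher in 50R were TUBA4A, an alpha tubulin, at 25.7 TPM against 10.2, UBE2S, a ubiquitin-conjugating enzyme of mitosis, at 60.2 against 25.2, POLR2L, an RNA polymerase subunit, at 21.9 against 6.89, and DANCR, a noncoding RNA, at 71.8 against 30.8. FAM220A was at 24.4 TPM against 7.11, FBXL19 at 22.6 against 8.99 and C1orf122 at 20.3 against 7.32. HIST1H3A, SNORD3C, MIR3687, SNORA68, SNORD97 and SNORD10 also passed the naming rule, and as short or multicopy transcripts they are uncertain. The stress response list had a median log2 fold of -0.67 (percentile 0), with 30 of 31 members lower in 50R. Lists above the upper percentile limit were cell cycle (median 0.44), MYC-linked ribosome biogenesis (0.33), oxidative phosphorylation (0.32), mitochondrial transcripts (0.35), Ara-C metabolism (0.25) and NRF2 and glutathione (0.23). Below the lower limit lay the stress response, stem cell surface antigen (-0.28), adhesion (-0.27), granulocyte and monocyte (-0.24) and type I interferon (-0.19) lists. 108 genes were at least 2-fold higher and 159 lower in 50R than in 3R, or 172 and 137 with TPM as deposited and 95 and 165 after the GC correction. Of the 108 and 159, 32 and 66 were protein-coding, and with protein-coding genes only, rescaled, the counts were 55 and 98. The NRF2 list lay at percentile 84.66 after the GC correction, with a median of 0.07.

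Both lines were set against the same WT library. 59 genes were at least 2-fold higher in both and 79 at least 2-fold lower in both. In 100 simulations of 3 libraries with no effect added, the numbers were 34.5 and 34.0 on average, with maxima of 54 and 57. Their spread came from 3R against 50R, so any real difference between these lines counted as noise, and they are no measured baseline. Independent lists of these sizes would share 1.18 and 2.90 genes. Pearson's r of the folds across genes was 0.552. The simulated r of 0.5 follows from a shared control with equal spread in each library, so it is no comparison with data. The covariance was 0.0912 against 0.0745 in the simulations, a difference of 0.0167 that rests on the same spread. The WT library cannot be split, so part of the overlap may come from the shared control. A common origin of 3R and 50R after WT, if there was one, was not taken into account either. MT2A, AC009302.2 and RNU2-22P were at least 2-fold from WT in opposite directions, higher in 3R and lower in 50R. The last of them is a pseudogene of a multicopy small RNA and is uncertain.

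**Figure D3:**
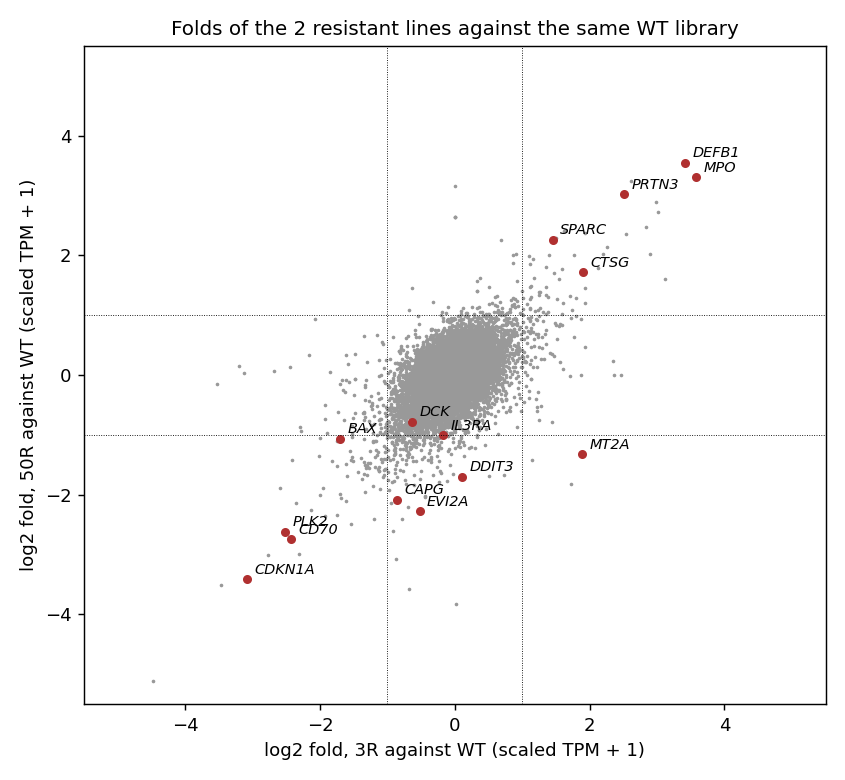
Each point is 1 gene, with its log2 fold against WT in 3R on the horizontal axis and in 50R on the vertical axis (log2 of scaled TPM + 1); dotted lines mark 2-fold, and red points are named genes. MPO and DEFB1 lie high in both lines (3.58 and 3.31, 3.42 and 3.55), CDKN1A and CD70 low in both, and MT2A is high in 3R (1.89) and low in 50R (-1.32).

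A test that treats 3R and 50R as samples of 1 resistant group asks which genes differed from WT by more than a spread that limma drew mostly from all genes together. The prior from all genes had 17.4 degrees of freedom, and each gene's own difference between the lines had 1. Among primary granule genes MPO rose by a log2 fold of 3.45 (SE 0.29; limma, adjusted p = 1.39e-06), PRTN3 by 2.76 (SE 0.30), ELANE by 2.15 (SE 0.29) and CTSG by 1.81 (SE 0.28), while AZU1 did not pass (0.14, SE 0.28). S100A8 rose by 1.88 (SE 0.28) and S100A9 by 1.54 (SE 0.33). DEFB1 rose by 3.49, SPARC by 1.85, HSD11B1 by 1.70, RHOXF2 by 1.40 and CDKN2C, an inhibitor of the G1 kinases, by 1.29, from 8.22 TPM in WT to 20.8 in 3R and 22.3 in 50R. CDKN1A (ENSG00000124762), the p21 inhibitor of cyclin-dependent kinases, fell from 16.3 TPM in WT to 1.05 in 3R and 0.625 in 50R (log2 fold -3.24, SE 0.29; limma, adjusted p = 3.54e-06). PHLDA3, a p53-induced inhibitor of AKT, fell from 13.7 TPM to 1.14 and 0.827, and PLK2, a kinase that p53 also induces, from 11.7 to 1.22 and 1.06. CD70, BAX, CACNA2D4 and MMP14 fell as well, with log2 folds of -2.59, -1.38, -1.41 and -1.41. LSP1, a leukocyte actin-binding protein, fell from 16.1 TPM to 2.43 and 1.14, SCHIP1 from 19.1 to 3.58 and 3.19, and ITGB2, the beta chain of leukocyte integrins, from 97.8 to 42.3 and 37.1. The cytokine TNF fell from 11.9 TPM to 4.12 and 2.35, the chemokine CCL3 from 3.57 to 0.918 and 0.660, and the glycolytic enzyme ENO2 from 9.73 to 3.94 and 2.54. HIST1H3F, HIST1H2BH, GOLGA8A, SNORD3D, HNRNPA1P48, CSPG4P13, BANF1P4, SEPT7P3 and RP11-380M21.2 were called too; they are copies or pseudogenes that share sequence with other genes and are uncertain. So were AL773541.1, CR753846.2 and RP11-136F16.1, clone-named genes listed at 0, 0.0111 and 0.0172 TPM in WT.

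In the p53 target list, limma called 3 members lower over all genes (CDKN1A, PHLDA3 and BAX) and 12 adjusted over the list alone, none higher. BBC3 (PUMA), a pro-apoptotic p53 target, was at 10.7, 4.64 and 2.92 TPM (limma, adjusted p = 0.0529 over all genes). In the granulocyte and monocyte list 6 members were called higher and 1 lower over all genes, and 7 higher and 5 lower adjusted over the list alone, with MPO, ELANE, PRTN3, CTSG, S100A8 and S100A9 higher and ITGAX lower in the first count, and MNDA higher and CD68 and CD86 among the lower in the second alone. Counts over all genes and adjusted over the list alone were 2 and 5 lower for NF-kB and inflammatory cytokines, 1 and 3 lower for adhesion, 1 and 4 lower for the BCL2 family and 1 and 1 lower for glycolysis. The kinase inhibitor list had 1 higher and 1 lower in both counts. The stemness set, the stress response list and the fibroblast and epithelial markers had 0 over all genes and 1 lower each over the list alone (CPXM1, ATF3 and PDGFRB). Every other fixed list but the stem cell antigens had 0 in both counts by limma, with 4 members of the cholesterol and interferon lists each, 5 mitochondrial transcripts and at most 3 of any further list below 0.05 before adjustment.

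In all, limma with Benjamini-Hochberg adjustment called 43 genes higher and 58 lower at 0.05, with 391 and 698 before adjustment, and all of them lay on the same side of WT in both lines. 30 of the 43 and 36 of the 58 had a mean below 5 TPM. The fit had 1 residual degree of freedom and assumes that the lone WT library varies like the resistant lines. It also takes 3R and 50R as independent samples, and a common origin of the 2 lines after WT, if there was one, was not taken into account. With 3R as the lone library limma called 0 genes (501 before adjustment) and with 50R 2 higher and 4 lower, and with the folds corrected for GC content it called 0 (lowest limma adjusted p 0.0625; 821 before adjustment), although all 101 genes kept their direction and an unadjusted p below 0.05. MPO then had a log2 fold of 3.69 (SE 0.29; limma, adjusted p = 0.0727) and CDKN1A of -3.10 (SE 0.29; limma, adjusted p = 0.107). The calls ended with the prior that limma estimated, whose degrees of freedom fell from 17.4 to 4.43 and SD from 0.236 to 0.194: with the prior of the uncorrected fit the corrected folds gave 42 higher and 53 lower by limma, and uncorrected folds with the prior of the corrected fit gave 0 (1028 before adjustment).

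**Figure D4:**
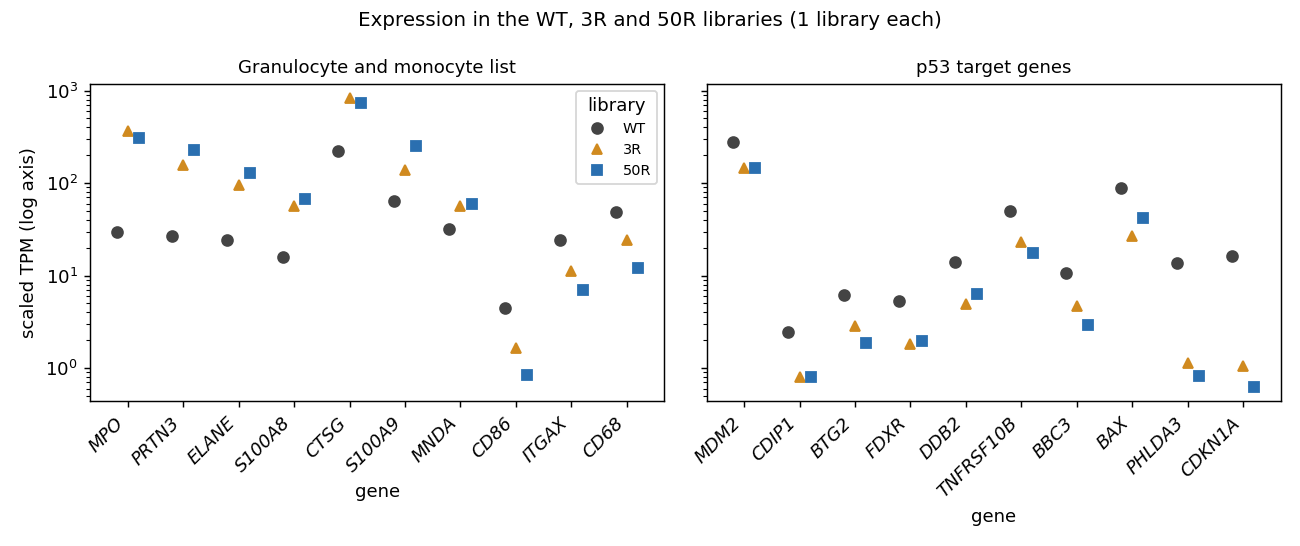
Scaled TPM (vertical log axis) in the WT (circles), 3R (triangles) and 50R (squares) libraries of the 10 granulocyte and monocyte genes and the 10 p53 target genes with the largest folds among those past 0.05 in limma's test adjusted over the list alone. MPO lies at 29.9, 368 and 307 TPM and CDKN1A at 16.3, 1.05 and 0.625.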

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

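The tests of scaling and GC content on the p53 genes, of the WT culture, of reads shared among paralogs and of mitochondrial ribosomal proteins were chosen after their results were seen. The second p53 and promyelocyte lists were chosen after the patterns but before their own values were seen, and the metallothionein list after values of some members were. The neutrophil and blood list was also chosen after the patterns, but LTF, CAMP, HBB, HBA1 and HBA2 were already in fixed lists, so not all its values were new.

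MT2A was flagged because its log2 fold was 1.89 in 3R and -1.32 in 50R. The difference between the lines was not tested, since each is 1 library. The 6 measured metallothioneins, near-identical copies of one another, had a median log2 fold of 1.66 in 3R and -0.42 in 50R.

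p53 target genes were lower in both resistant lines. The list's medians were -0.73 in 3R and -0.84 in 50R. Leaving out the scaling moved the median of all genes by 0.09 log2 in 3R and 0.16 in 50R, and the lowest median of a GC bin was -0.40, in 3R. Shifts of that size are unlikely to account for the whole pattern, and a check against them could hardly have come out otherwise. Over both lines, the scalings run and the GC correction the highest median of the list was -0.63 log2. A second list of targets that shares no gene with the first lay at percentile 0 of random lists in both lines, with medians of -0.29 and -0.27 (-0.15 and -0.25, at percentiles 0.01 and 0, after the GC correction). Of its 61 measured members 47 were below WT in 3R and 51 in 50R, with 14 and 10 above, and 1 and 3 were at least 2-fold lower. These values would follow from lower p53 output in the resistant lines, as a hypothesis. The same values would follow from a p53 response in the WT culture at harvest, and with 1 WT library these explanations cannot be told apart. No mutation or protein data were analysed here.

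Of the azurophil granule genes, MPO, PRTN3, ELANE and CTSG were more than 2-fold higher in both lines, while AZU1, at 273 TPM in WT, 280 in 3R and 322 in 50R, was not. Reads shared among the neighbouring paralogs ELANE, PRTN3 and AZU1 do not account for MPO, which is no paralog of theirs and had a log2 fold of at least 3.31 in each line. Mature neutrophils or blood in the cultures would bring their abundant transcripts, but the highest of 10 such genes reached 0.42 TPM (CAMP, in 3R). LTF, CAMP, HBB, HBA1 and HBA2 among them were also in the fixed lists, so their levels were no fresh test. Further promyelocyte genes had medians at percentiles 100 and 99.07, consistent with a shift towards the promyelocyte stage as a hypothesis, though CEACAM6 was lower in both lines and the 50R percentile was 63.42 with genes of at least 10 TPM. Whether resistance, clonal selection or separate culture brought it was not tested.

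Oxidative phosphorylation genes were higher in 50R. Among random lists matched on expression and transcript length the list lay at percentile 100, and among lists matched on expression and GC content also at 100. Folds in 50R hardly followed length across genes (Spearman's rho -0.0153) and followed GC content weakly (-0.144). Trends this weak are unlikely to account for a median of 0.41, and these checks could hardly have come out otherwise. The 74 measured MRPL and MRPS genes, mitochondrial ribosomal proteins, had a median log2 fold of 0.40 at percentile 100, but that test was chosen after its result was seen, so whether mitochondrial gene expression was higher in 50R as a whole stays open. The mitochondrial transcripts, a list fixed as a sign of RNA quality, were also higher in 50R (median 0.76, percentile 100), with 3 of 15 below WT. Neither RNA quality, reads shared with nuclear copies, nor culture density or growth rate at harvest was tested.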

How the results depend on the processing

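The results with each gene ID on its own, with protein-coding genes only, with folds corrected for GC content and with exchanged priors were chosen after seeing the data. No paired analysis was possible because each line has 1 library. Thinning to equal depth, the DESeq2 Wald test, limma-voom and the most abundant transcript per gene were not run, since they need counts or transcripts that gene-level TPM does not hold, and for the same reason the limits set by depth cannot be given. Of 825 list medians under the alternatives 791 stayed the same by the percentile limits, and of 3398 folds of named genes 3317 did by the size rule, with 0 reversed. p53 target genes stayed below the lower limit in both lines throughout, with medians from -0.92 to -0.55 in 3R and from -1.02 to -0.67 in 50R.

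Fold counts moved with filter and pseudocount by construction, as fewer genes or smaller folds of low genes remain. With a mean of at least 10 TPM the genes higher and lower were 34 and 47 in 3R, 36 and 95 in 50R, 44 and 59 in 50R against 3R, and 14 and 16 in both lines. With pseudocount 2 they were 77 and 105 in 3R, 68 and 89 in 50R against 3R, and 26 and 47 in both lines, with 72 higher in 50R. Pseudocount 0.5 gave 263 lower in 3R, 173 higher in 50R against 3R and 96 higher in both. Pseudocount 0.1 gave 335 and 390 in 3R, 289 and 524 in 50R, 255 and 368 in 50R against 3R, and 153 and 165 in both. TPM as deposited gave 264 higher in 50R and 172 higher in 50R against 3R, as no scaling lifts the resistant lines. Protein-coding genes only gave 55 and 98 in 50R against 3R, with fewer genes and other scaling factors at once, and the cause was not tested.

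The limma counts, 43 higher and 58 lower, were the least stable. They were 25 and 31 with median-of-ratios scaling, 15 and 12 with TPM as deposited, 14 and 23 with at least 10 TPM, 14 and 13 with pseudocount 2, and 15 and 20 with each gene ID on its own, and limma-trend called 93 lower. With no filter they were 0 and 0 (limma, 3134 before adjustment) and with folds corrected for GC content 0 and 0 (821), with 3R standing alone 0 and 0 (501) and with 50R standing alone 2 and 4 (895). For the GC correction the fitted prior accounts for it: corrected folds with the prior of the uncorrected fit gave 42 and 53, and uncorrected folds with the prior of the GC-corrected fit 0 and 0 (limma, 1028 before adjustment). For the others the cause was not tested.

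Of list medians past a percentile limit, 3 changed sign, all in 50R: with TPM as deposited haematopoietic transcription factors were at 0.00523 and cytokine receptor and JAK-STAT genes at 0.0051, and with at least 10 TPM granulocyte and monocyte genes at 0.104. Leaving out the scaling moved the median of all genes in 50R up by 0.163 log2, and the factor and JAK-STAT lists stayed below the lower percentile limit there. The other medians named here crossed a percentile limit, and the cause was not tested. With TPM as deposited the interferon list in 50R passed it (0.0148). With the GC correction Ara-C metabolism (0.171) and haematopoietic factors (-0.143) in 50R and NRF2 genes in 50R against 3R (0.0745) no longer passed. In 3R the class II (-0.26), cell cycle (0.0804) and stem cell antigen (-0.232) lists then did, as did interferon in 50R (-0.132) and acetylation (-0.196), JAK-STAT (-0.177) and DNA repair (0.219) in 50R against 3R. With at least 10 TPM Ara-C (0.231), interferon (-0.206) and NRF2 (0.235) in 50R against 3R, NF-kB in 3R (-0.0465) and 50R (-0.167), and JAK-STAT (-0.062) and haematopoietic factors (-0.169) in 50R no longer passed, while interferon in 50R (-0.412) did. With no filter granulocyte and monocyte genes in 50R (-0.00465) no longer passed, and haematopoietic factors (-0.127), class II (-0.252) and interferon (0.104) in 3R did. Protein-coding genes only brought interferon in 3R (0.138) and BCL2 (-0.222), acetylation (-0.132) and NRF2 (0.173) in 50R past a limit, pseudocount 0.1 interferon in 50R (-0.169) and class II in 3R (-0.31), and pseudocount 2 BCL2 in 50R (-0.19) and class II in 3R (-0.224).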

Other observations

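The test of chromosomes after the GC correction, and the lists and families in this part, were chosen after the data were seen.

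Genes of the cytosolic ribosome were lower in 50R. The 82 ribosomal protein genes had a median log2 fold of -0.62, with 78 of them below WT (median -0.43 with TPM as deposited and -0.62 after the GC correction), and in 3R the median was -0.23 (-0.12 with TPM as deposited and -0.18 after the GC correction). Their share of the total TPM was 14.1% in WT, 13.1% in 3R and 10.5% in 50R. RPL13A was at 2700 TPM in WT, 2000 in 3R and 1520 in 50R, and EEF1A1, a translation elongation factor, at 10500, 10800 and 6090; both have many processed pseudogenes. Mitochondrial ribosomal protein genes went the other way in 50R, with 10 of 74 below WT. Tubulin genes, which form microtubules, had a median of 0.75 in 50R (percentile 100) and -0.18 in 3R (percentile 11.79), with TUBA1B at 276, 254 and 522 TPM in WT, 3R and 50R; TUBA1A, at 87.3, 48.0 and 47.6, was the exception.

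Chaperones of the endoplasmic reticulum parted the resistant lines. The 17 genes had a median log2 fold of 0.45 in 3R (percentile 100) and -0.25 in 50R (percentile 0.99), with 14 below WT and 3 above in 50R. HSP90B1 was at 316, 614 and 291 TPM in WT, 3R and 50R, and HSPA5 (BiP) at 44.6, 67.3 and 31.8. CALR, calreticulin, at 694, 1460 and 864, was above WT in both lines. The directions of the list medians stayed opposite under every alternative, though the 50R median came as near to WT as -0.05. The metallothionein medians lay in the same directions, while MT1G, at 2.67, 17.8 and 2.67 TPM, was level with WT in 50R. These are differences between single libraries and were not tested. The summed histone H3 genes were at 853, 545 and 1031 TPM and the H2B genes at 3301, 2511 and 3617. HIST1H3F and HIST1H2BH were thus far lower in both lines while their families were not lower in 50R.

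Whether a resistant line had gained or lost a whole chromosome was asked of the medians of protein-coding genes. Before any correction, the 862 genes of chromosome 19 had a median log2 fold of -0.21 in 3R, and those of chromosome 22 of -0.17, both at percentile 0 of random gene sets, while chromosome 4 was at 0.14. These chromosomes differ in GC content, with medians of 59.3%, 57.1% and 43.2%. The value of chromosome 19 passed the size first set for a gain or loss, and the test was then repeated on corrected folds. After the GC correction the median of largest size was -0.0702 (chromosome 13 in 50R, percentile 0.11), and that of chromosome 19 in 3R was -0.03, still at percentile 0, so a gain or loss of a whole chromosome is unlikely on these values, and most of the uncorrected pattern went with the GC trend. Smaller segments were not excluded.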
